A study of Mus musculus with 4 samples.

How the data were processed

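RNA was measured in 4 libraries of thymic Tregs from mice, 2 from Aire KO and 2 from WT animals. Per the labels' protocols, CD8-positive and CD19-positive cells were depleted with magnetic beads, CCR6-positive CD4-positive CD8-negative CD25-positive cells were sorted by flow cytometry, and libraries were made with a stranded poly(A) kit and read as 50 bp single-end reads. The submitters' processing notes name TopHat2, Cufflinks and Cuffdiff and the genome build mm10, without versions or the role of each tool. The annotation, and whether strand was used in assigning reads, are not given in the sources used here. Per the file headers, the deposited values are FPKM per gene, with the lower and upper bound of an interval and a status. Each library had a separate table. FPKM are by definition fragments per kilobase of transcript, scaled to the mapped fragments of the library. This divides each gene by its length and each library by its total, so a few abundant genes can lower all others. Whether the submitters' tools scaled the libraries in another way cannot be told, as the role of each tool is not given. Names of microRNAs and other small RNAs took 18.5%, 19.0%, 18.3% and 18.0% of the summed FPKM of Aire KO 1 and 2 and WT 1 and 2, and Mir682 alone took 10.8% to 12.9%.

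The depth of each library was estimated from the interval widths, taken as 2 SD of a Poisson count on either side. Among low genes, 64.9% to 67.0% of the fragment numbers implied in this way were whole within 0.02, so FPKM were not turned back into counts and no count model was used. The estimates of 19.7 to 21.6 M (mega) fragments put the libraries at nearly equal depth. Whether the intervals cover more than counting error cannot be told, and they were not taken to measure the spread between libraries.

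Each table held 24346 gene names. The values of 280 names listed more than once were summed, and 4 names with a status other than OK in any library were left out. Values were used as log2(FPKM + 1) with no further scaling, and genes with a mean of at least 1 FPKM over the 4 libraries were tested, 10760 in all. Aire KO was compared with WT with limma 3.58.1 in R 4.3.3, with an intensity trend in the empirical Bayes step (prior degrees of freedom 4.41) and Benjamini-Hochberg adjustment over genes at 0.05. The limma and camera tests were two-sided; Fisher's exact tests on called genes in a region were one-sided. Replicate numbers were not used to pair libraries because no label ties equal numbers to an animal, a litter or a day. No label says that the libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. An exact 0 can be a failed estimate in such files, so genes at 0 throughout a group are described as listed at 0, with each library's value and no fold.

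Before the data were examined, 25 gene lists were fixed: Treg core, effector and tissue Treg, resting T cell, immature thymocyte, chemokine receptors and homing, T cell receptor activation and immediate early, proliferation, interferon response, NF-kappaB and TNF receptor, IL-2 and STAT5, RORgammat and type 17, TGF-beta, apoptosis, glycolysis, oxidative phosphorylation, cholesterol synthesis, heat shock and stress, thymic epithelium and stroma, B cell and plasma cell, dendritic cell, macrophage and myeloid, NK, CD8 and gamma-delta T cell, red cell, ribosomal protein, mitochondrially encoded and histone. The 23 lists with at least 5 tested members were compared with all other genes by limma's camera with an inter-gene correlation of 0.01, adjusted over the 23 lists, and again with the correlation estimated for each list. The estimate rests on the 2 residual degrees of freedom of 4 libraries, and no list passed with it, though 2 did at an unadjusted p under 0.05. Members were counted as higher or lower after adjustment over all tested genes and again after adjustment over the list alone. Some genes are in several lists.

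Genes were named by a rule also fixed beforehand. It takes Aire and the genes of the sort, the 12 genes with the largest log2 difference in each direction among those past the threshold, the 4 members with the smallest p in the direction of each list that passed, and the largest rise and fall among members with a mean of at least 5 FPKM in each list that did not. Predicted genes, small RNAs and variable segments of antigen receptors were counted and not named. Other genes named were chosen after their values were seen: members that went against their list, the sex-linked genes, Hba-a1 and those introduced as such in the additional observations. Coordinates are those of the files, in mm10.

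The alternatives were pseudocounts of 0.1 and 5, no filter and a filter at a mean of 5 FPKM, quantile normalization, trimmed-mean (TMM) scaling of FPKM, limma without the trend, the replicate number as a block, genes listed more than once left out, genes with another status kept, each library left out in turn, and the estimated correlation. Without a library, its group had 1 sample, assumed to vary like the other group. The procedure was tested on simulated data for the comparison of Aire KO with WT, with 10760 genes of which 200 were changed. It recovered 62% of the genes changed 1.5-fold and 92% of those changed 2-fold, and 9.41% of its calls were false. With no gene changed it made 2 calls and passed 0 lists. The simulated genes varied independently of each other, so the lists were not tested under correlation between genes. Tables were read with Python 3.11.15 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.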

Results

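Thymic regulatory T cells (Tregs) were sorted from 6-week-old mice lacking Aire and from wild-type (WT) mice, and their polyadenylated RNA was sequenced. Aire is the transcription factor through which medullary thymic epithelial cells display tissue-restricted antigens to developing T cells. The sort took CD4-positive, CD8-negative, CD25-positive cells bearing CCR6, a chemokine receptor used here to mark recirculating cells, which return to the thymus. Whether the sorted cells had returned was not tested. Each genotype had 2 libraries, Aire KO 1 and 2 and WT 1 and 2, and the question was how the RNA of these cells differed between the genotypes. The files list FPKM and no read totals. The widths of the FPKM intervals correspond to about 21.6 M and 20.8 M fragments for Aire KO 1 and 2 and 19.7 M and 20.5 M for WT 1 and 2. At least 1 FPKM was listed for 10557, 10575, 10805 and 10772 genes in the same order. Values of log2(FPKM + 1) correlated across genes with r = 0.973 between the Aire KO libraries and 0.958 between the WT libraries, against 0.934 to 0.948 between genotypes; genes are not independent replicates.

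Aire itself (mm10 chromosome 10, 78030022 to 78043610, a protein-coding gene) was listed at 0.208 and 0.163 FPKM in Aire KO 1 and 2 and at 0.0502 and 0.0204 FPKM in WT 1 and 2. These levels, below 1 FPKM in every library and with overlapping intervals, do not check the genotype labels. The genes of the sort were high in all 4 libraries, except the excluded marker Cd8a. Foxp3, the Treg lineage factor, measured 316 ± 15.3 FPKM in Aire KO and 352 ± 22.2 in WT (mean ± SD, n = 2 each), a log2 difference of -0.15 (SE 0.075, limma adjusted p = 0.221). Log2 differences were -0.13 for Il2ra, which encodes CD25 (adjusted p = 0.288), -0.17 for Cd4 (adjusted p = 0.212) and -0.32 for Cd8a (adjusted p = 0.422), none past the threshold. Without WT 1, Cd4 passed at an adjusted p of 0.0411 (0.0411 to 0.546 over its alternatives). The Y-linked genes Eif2s3y, Ddx3y, Kdm5d and Uty were listed at 0 in both Aire KO libraries, at 15.1, 7.34, 2.77 and 2.54 FPKM in WT 1 and at 1.00, 0.773, 0.202 and 0.194 FPKM in WT 2. Xist, transcribed from the inactive X chromosome, measured 4.02, 4.64, 5.23 and 3.66 FPKM in Aire KO 1 and 2 and WT 1 and 2. Y-linked RNA thus separated the genotypes and also differed between the WT libraries.

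In Aire KO cells, genes of the interferon response and of resting, circulating T cells were higher, and genes of effector and tissue Tregs were lower. These 3 lists passed camera with its preset correlation, not with an estimated correlation (adjusted p = 0.456, 0.357 and 0.357), and 11 of 21 measured markers of dendritic cells, macrophages and other myeloid cells were lower in the same libraries. Usp18, a negative regulator of interferon signalling, rose 8.01-fold, from 7.10 ± 0.256 to 63.9 ± 3.85 FPKM (SD, n = 2 each). S100a4, a calcium-binding protein of effector T cells, was 4.32-fold lower, at 80.5 ± 7.67 FPKM against 350.2 ± 17 in WT. Sell, the lymph node homing receptor CD62L, was 2.09-fold higher, and Ccr6, although part of the gate, was 1.83-fold lower. The inducible heat shock genes Hspa1a and Hspa1b had the largest differences of the named genes, 106-fold and 107-fold lower.

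Of 10760 genes tested, 827 were higher and 924 lower in Aire KO (limma with an intensity trend, adjusted p under 0.05), and 97 and 310 of these differed at least 2-fold. All folds are on the log2(FPKM + 1) scale, which understates the change of low genes. At an unadjusted p under 0.05 there were 3380 genes against 538 expected by chance, of which 320 were at least 1.5-fold higher and 665 at least 1.5-fold lower. With a pseudocount of 5 these were 182 and 351, and with a mean of at least 5 FPKM the lower ones numbered 358. The groups did not overlap for 60.5% of tested genes, where chance gives 33.3% for 2 against 2. The number called depended on single libraries, falling to 171 higher and 355 lower without Aire KO 2 and to 232 and 442 without Aire KO 1. With no filter on low values, 316 genes were higher and 471 lower, and more genes were higher than lower without WT 2 (751 and 612) and with a mean of at least 5 FPKM (762 and 641).

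**Figure D1:**
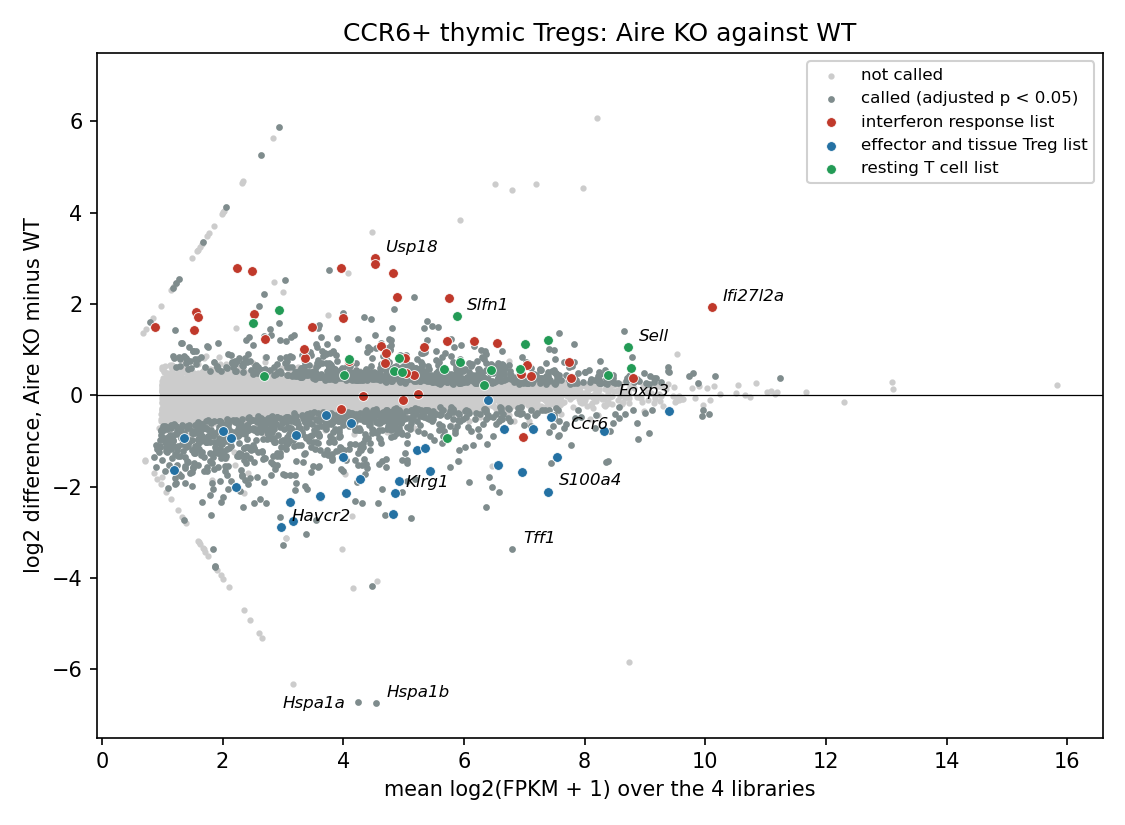
Log2 difference (Aire KO minus WT) of each tested gene against its mean log2(FPKM + 1) over the 4 libraries. Dark grey points passed adjusted p under 0.05, coloured points belong to 3 of the gene lists, and 2 genes lie beyond the vertical range. The interferon list (red) lies mostly above 0 and the effector and tissue Treg list (blue) below it.

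The interferon response list was the one with the highest mean difference: 35 of its 41 measured members rose, 1 fell and 5 did not pass (36 and 2 adjusted over the list alone). Its mean log2 difference was 1.20 (camera adjusted p = 3.18e-20, and adjusted p = 0.456 with an estimated correlation). Besides Usp18 (mm10 chromosome 6, 121245906 to 121270917), Ifit1 rose 7.37-fold, from 7.52 ± 1.07 to 61.5 ± 1.66 FPKM (SD, n = 2 each). Rtp4 rose 6.44-fold and the ubiquitin-like modifier Isg15 4.45-fold. The member that fell was Ly6a, an activation marker also called Sca-1, with a log2 difference of -0.92 (adjusted p = 0.00193). Among the 12 genes that rose most, Ifit3 (log2 difference 2.80), Oasl1 (2.78), Ifit1bl1 (2.74), Oasl2 (2.73), Ifit3b (2.52) and Pydc4 (2.22) are also known to be interferon-inducible. Ifit3 and Ifit3b, like Ifit1 and Ifit1bl1, are related genes whose reads can be divided between them. The other 3 of the 12 rested on low values. S100a8 and S100a9, neutrophil proteins, were listed at 0 in both WT libraries, with 6.99 and 3.25 FPKM for S100a8 and 5.11 and 3.28 FPKM for S100a9 in Aire KO 1 and 2. Rpl26, a ribosomal protein gene, was listed at 2.73 and 7.17 FPKM in Aire KO 1 and 2 and at 0.000222 and 0.000218 in WT, values too low for a gene that every cell uses, and it did not pass with no filter on low values (adjusted p = 0.0694, the highest over its alternatives).

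Effector and tissue Treg genes formed the list that fell most: 29 of 32 measured members were lower, 0 higher and 3 did not pass (31 lower adjusted over the list alone). Its mean log2 difference was -1.43 (camera adjusted p = 1.27e-24, and adjusted p = 0.357 with an estimated correlation). S100a4 (log2 difference -2.11), S100a6 (-1.52), the growth factor gene Areg (-2.75) and the transcription factor Maf (-2.02) had the smallest p-values. Havcr2, which encodes the inhibitory receptor TIM-3, fell from 20.7 ± 5.56 to 1.88 ± 0.219 FPKM (SD, n = 2 each), a log2 difference of -2.89 (adjusted p = 0.000448). Markers of dendritic cells, macrophages and other myeloid cells were lower in the same libraries (11 of 21 measured).

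Resting T cell genes moved the other way, with 16 of 20 measured members higher, 1 lower and 3 not passed (18 and 1 adjusted over the list alone). Their mean log2 difference was 0.74 (camera adjusted p = 1.04e-11, and adjusted p = 0.357 with an estimated correlation). Slfn1 (log2 difference 1.74), Sell (1.06), S1pr1 (1.12), the receptor for egress from lymphoid organs, and Klf2 (1.22), the transcription factor that drives S1pr1 and Sell, had the smallest p-values. Sell reached 610.2 ± 10.4 FPKM in Aire KO against 292 ± 5.33 in WT (SD, n = 2 each). Il7r, the interleukin 7 receptor, was the member that fell (log2 difference -0.92, adjusted p = 0.00442).

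**Figure D2:**
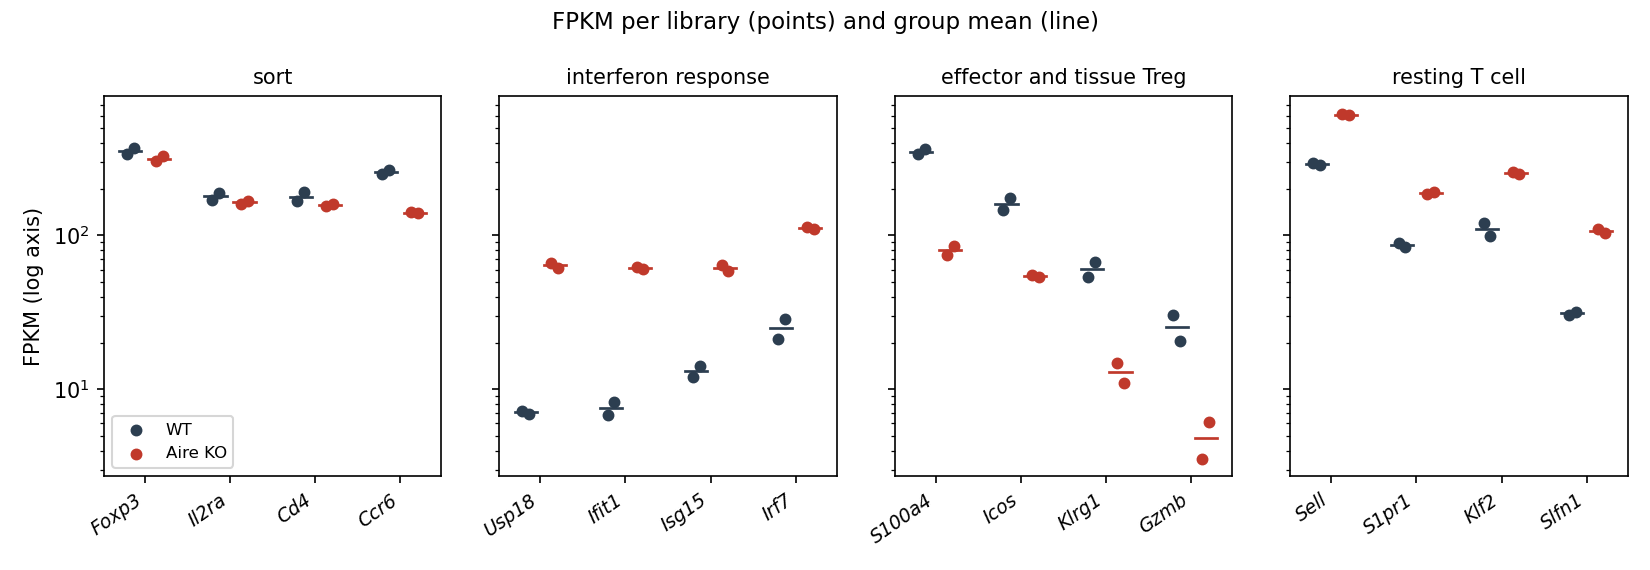
FPKM (log axis) of each library (points) and group mean (line) for genes of the sort and of 3 lists. The 2 libraries of a genotype lie close together, Foxp3, Il2ra and Cd4 differ little between genotypes, and Ccr6 is lower in both Aire KO libraries (143 and 139) than in WT (250.3 and 266).

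Of 29 measured chemokine receptor and homing genes, 15 fell, 6 rose and 8 did not pass (17 and 6 adjusted over the list alone; mean log2 difference -0.62, camera adjusted p = 0.000243). The list's adjusted p was 0.456 with an estimated correlation. Cxcr6 fell most, from 62.9 ± 5.67 to 9.42 ± 0.786 FPKM (SD, n = 2 each), followed among the smallest p-values by Ccr2 (log2 difference -2.31), the integrin gene Itgae, which encodes CD103 (-2.01), and Ccr4 (-1.59). Ccr6 (mm10 chromosome 17, 8236043 to 8257129) measured 141 ± 2.82 FPKM in Aire KO and 258 ± 11.3 in WT (SD, n = 2 each), a log2 difference of -0.87 (SE 0.066, limma adjusted p = 0.000853). The list of RORgammat and type 17 genes, which holds Ccr6, had 7 of 12 measured members lower, 1 higher and 4 not passed (8 and 1 adjusted over the list alone). Its mean was -0.87 (camera adjusted p = 1.19e-05, and adjusted p = 0.380 with an estimated correlation). The leukotriene B4 receptor Ltb4r1 (-2.37), Maf (-2.02), the nuclear receptor Rora (-1.35) and Rorc (-1.24), which encodes RORgammat, were among those lower. With no filter on low values Rorc did not pass (limma adjusted p = 0.0858).

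Core Treg genes went both ways, with 6 of 20 measured lower, 3 higher and 11 not passed (also 6 and 3 adjusted over the list alone). The mean log2 difference was -0.24 (camera adjusted p = 0.0260, and adjusted p = 0.649 with an estimated correlation). Itgae, the actin-capping protein gene Capg (log2 difference -0.96), the inhibitory receptor Ctla4 (-0.72) and the ectonucleotidase Entpd1 (-0.85) were lower. The list did not pass without Aire KO 1 (adjusted p = 0.0531) or with no filter on low values (adjusted p = 0.0928; 0.00207 to 0.649 over its alternatives).

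The heat shock and stress list had 6 of 17 measured members lower, 0 higher and 11 not passed (8 lower adjusted over the list alone). Its mean log2 difference of -1.02 and median of -0.22 were far apart because of the Hspa1 genes (camera adjusted p = 0.000219, and adjusted p = 0.503 with an estimated correlation). Hspa1b (mm10 chromosome 17, 34956429 to 34959238) fell from 239.9 ± 11.9 to 1.24 ± 0.0280 FPKM, and Hspa1a (34969359 to 34972156) from 193 ± 9.69 to 0.841 ± 0.136 FPKM (SD, n = 2 each). The folds were 107 and 106 (adjusted p = 6.84e-07 and 8.99e-07). Hspa1l, the neighbouring relative of both (34972703 to 34979228), fell from 10.6 ± 0.628 to 0.116 ± 0.0146 FPKM. Hspa1a and Hspa1b are near-identical copies, so the division of reads among them is uncertain. Atf4 and Dnajb1 had log2 differences of -0.52 and -0.56; neither passed without Aire KO 2 (adjusted p = 0.0863 and 0.140, the highest over their alternatives) or without Aire KO 1 (0.0563 and 0.0522), and Dnajb1 also missed with no filter on low values (0.0830).

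T cell receptor activation and immediate early genes were lower for 12 of 28 measured members, higher for 5 and not passed for 11 (14 and 7 adjusted over the list alone). The mean log2 difference was -0.40 (camera adjusted p = 0.00160, and adjusted p = 0.503 with an estimated correlation). Ppp1r15a (log2 difference -1.87), Jun (-1.57), the phosphatase Dusp1 (-2.12) and Junb (-1.44) had the smallest p-values. The 5 higher members were Dusp2 (0.72), Myc (0.70), Egr1 (0.66), Dusp6 (0.64) and Ier2 (0.39). Genes of NF-kappaB and TNF receptor signalling were lower for 8 of 26, higher for 1 and not passed for 17 (10 and 3 adjusted over the list alone; mean -0.23, camera adjusted p = 0.00183). Their adjusted p was 0.617 with an estimated correlation. The NF-kappaB inhibitor Tnfaip3 (log2 difference -1.08), the survival gene Bcl2l1 (-0.70), Icam1 (-0.77) and Tnfsf11, which encodes RANKL (-0.76), were lower. Tnfsf11 did not pass without Aire KO 2 (adjusted p = 0.0559, the highest over its alternatives). Other genes among the 12 that fell most were the trefoil peptide gene Tff1 (chromosome 17, 31161396 to 31165053), at 33.7 ± 2.46 FPKM against 365 ± 96.5 in WT (SD, n = 2 each), the prohormone convertase Pcsk1 (log2 difference -3.27), Ier5l (-2.74), Ttc39c (-2.70) and the metallothionein Mt1 (-2.66). Retnla was listed at 0 in both Aire KO libraries and at 4.68 and 6.67 FPKM in WT 1 and 2.

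Proliferation genes were lower for 16 of 34 measured, higher for 1 and not passed for 17 (21 and 1 adjusted over the list alone). Their mean log2 difference was -0.31 (camera adjusted p = 2.42e-09). The list's adjusted p was 0.357 with an estimated correlation. Tk1, a thymidine kinase of S phase, had a log2 difference of -0.75, and Mcm3, Rrm2 and Birc5 had -0.51, -0.52 and -0.43. Without Aire KO 1 the adjusted p of Mcm3, Rrm2 and Birc5 was 0.0522, 0.0738 and 0.106, and without Aire KO 2 it was 0.0687, 0.0628 and 0.10, against lows of 0.000293, 0.000582 and 0.00208 over their alternatives. Glycolysis genes were lower for 10 of 21, higher for 0 and not passed for 11 (12 lower and 1 higher adjusted over the list alone), with a mean of -0.31 (camera adjusted p = 1.57e-05, and adjusted p = 0.357 with an estimated correlation). Tpi1 (log2 difference -0.80), Aldoa (-0.79), Aldoc (-1.15) and Pgam1 (-0.49) were lower; Pgam1 did not pass without Aire KO 2 (adjusted p = 0.0894, the highest over its alternatives). Histone genes, most of whose messages lack a poly(A) tail, were lower for 14 of 67, higher for 1 and not passed for 52 (15 and 1 adjusted over the list alone). Their mean was -0.31 (camera adjusted p = 1.65e-05, and adjusted p = 0.456 with an estimated correlation). Hist1h4n (log2 difference -1.18), H1f0 (-1.04), Hist1h3a (-0.71) and Hist1h2bg (-0.60) were lower. Hist1h3a and Hist1h2bg did not pass without Aire KO 2 (adjusted p = 0.0811 and 0.105, the highest over their alternatives) or without Aire KO 1 (0.0588 and 0.0783). Hist1h2bg missed without WT 2 too (0.0567), and with no filter on low values H1f0, Hist1h3a and Hist1h2bg had 0.0576, 0.0569 and 0.0634.

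Ribosomal protein genes rose together by a small amount, with 61 of 80 measured higher, 0 lower and 19 not passed (71 higher adjusted over the list alone). Their mean log2 difference was 0.39 (camera adjusted p = 8.05e-25, and adjusted p = 0.357 with an estimated correlation). Rpl9 (log2 difference 0.73), Rps27a (0.60), Rps7 (0.59) and Rps18 (0.62) had the smallest p-values. Processed copies of these genes in the genome can take up their reads, so single members are uncertain, and Rps7 and Rps18 did not pass without Aire KO 2 (adjusted p = 0.0587 and 0.0594, the highest over their alternatives). Oxidative phosphorylation genes were higher for 6 of 51, lower for 0 and not passed for 45 (6 higher adjusted over the list alone), with a mean of 0.14 (camera adjusted p = 5.30e-05, and adjusted p = 0.532 with an estimated correlation). Ndufb2, Ndufa6, Uqcrq and Cox7a2, respiratory chain subunits, had log2 differences of 0.52, 0.47, 0.42 and 0.37. Without Aire KO 2 their adjusted p was 0.0687, 0.0798, 0.0956 and 0.147, the highest over their alternatives, and without Aire KO 1 it was 0.0638, 0.0915 and 0.105 for Ndufa6, Uqcrq and Cox7a2.

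Markers of other cells differed as well. Of the dendritic cell, macrophage and myeloid list, 11 of 21 measured members were lower, 2 higher and 8 not passed (14 and 2 adjusted over the list alone), with a mean log2 difference of -0.64 (camera adjusted p = 1.55e-06, and adjusted p = 0.357 with an estimated correlation). Fcer1g (log2 difference -1.68) and the antigen presentation genes Cd74 (-1.48), H2-Eb1 (-1.56) and H2-Ab1 (-1.51) were lower, Cd74 at 103 ± 6.43 FPKM against 289.8 ± 47.1 in WT (SD, n = 2 each). The members that were higher were S100a8 and S100a9, listed at 0 in WT. The lists of B and plasma cells, of NK, CD8 and gamma-delta T cells, of thymic epithelium and stroma, and of immature thymocytes did not pass (camera adjusted p = 0.590, 0.590, 0.662 and 0.899). None of 6 measured B cell genes passed over all genes, while 1 was higher and 1 lower adjusted over the list alone. Cd79b had a log2 difference of -0.08 and Ly6d of -0.29, and Ly6d passed without WT 2 (adjusted p = 0.0202; 0.0202 to 0.851 over its alternatives). Of 11 NK, CD8 and gamma-delta T cell genes, 3 were higher and 2 lower (5 and 2 adjusted over the list alone), including the chemokines Xcl1 (1.15) and Ccl5 (-0.52); the mean was 0.04 and the median -0.01. Ccl5 did not pass under 5 of its 16 alternatives, among them those without Aire KO 1 (adjusted p = 0.0876), without Aire KO 2 (0.188, the highest), with no filter on low values (0.115) and without the intensity trend (0.0608). Pecam1 (0.67) was higher and Epcam (-0.48) lower among 5 epithelial and stromal genes (also 1 and 1 adjusted over the list alone). Without Aire KO 2 neither passed (adjusted p = 0.0586 and 0.105), nor did Epcam without Aire KO 1 (0.113, the highest over its alternatives), while with no filter on low values the list was lower at an adjusted p of 0.0220. Rorc (-1.24) was 1 of 2 immature thymocyte genes lower out of 20, with 0 higher (the same numbers adjusted over the list alone); the mean was -0.08 and the median 0.04. Rorc did not pass with no filter on low values (adjusted p = 0.0858, the highest over its alternatives). Sox4, at a log2 difference of 0.57 (adjusted p = 0.0502), passed under 6 of its 16 alternatives, among them those with a pseudocount of 0.1 (adjusted p = 0.0433), a mean of at least 5 FPKM (0.0496), small RNA names left out (0.00622) and WT 1 left out (0.00488; 0.00488 to 0.254 over its alternatives). Of the red cell list, Hba-a1 alone was measured, at 12.8 FPKM in WT 1 and 0.148 FPKM in Aire KO 2, and it was listed at 0 in the other libraries. The files held no name of the mitochondrially encoded list.

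**Figure D3:**
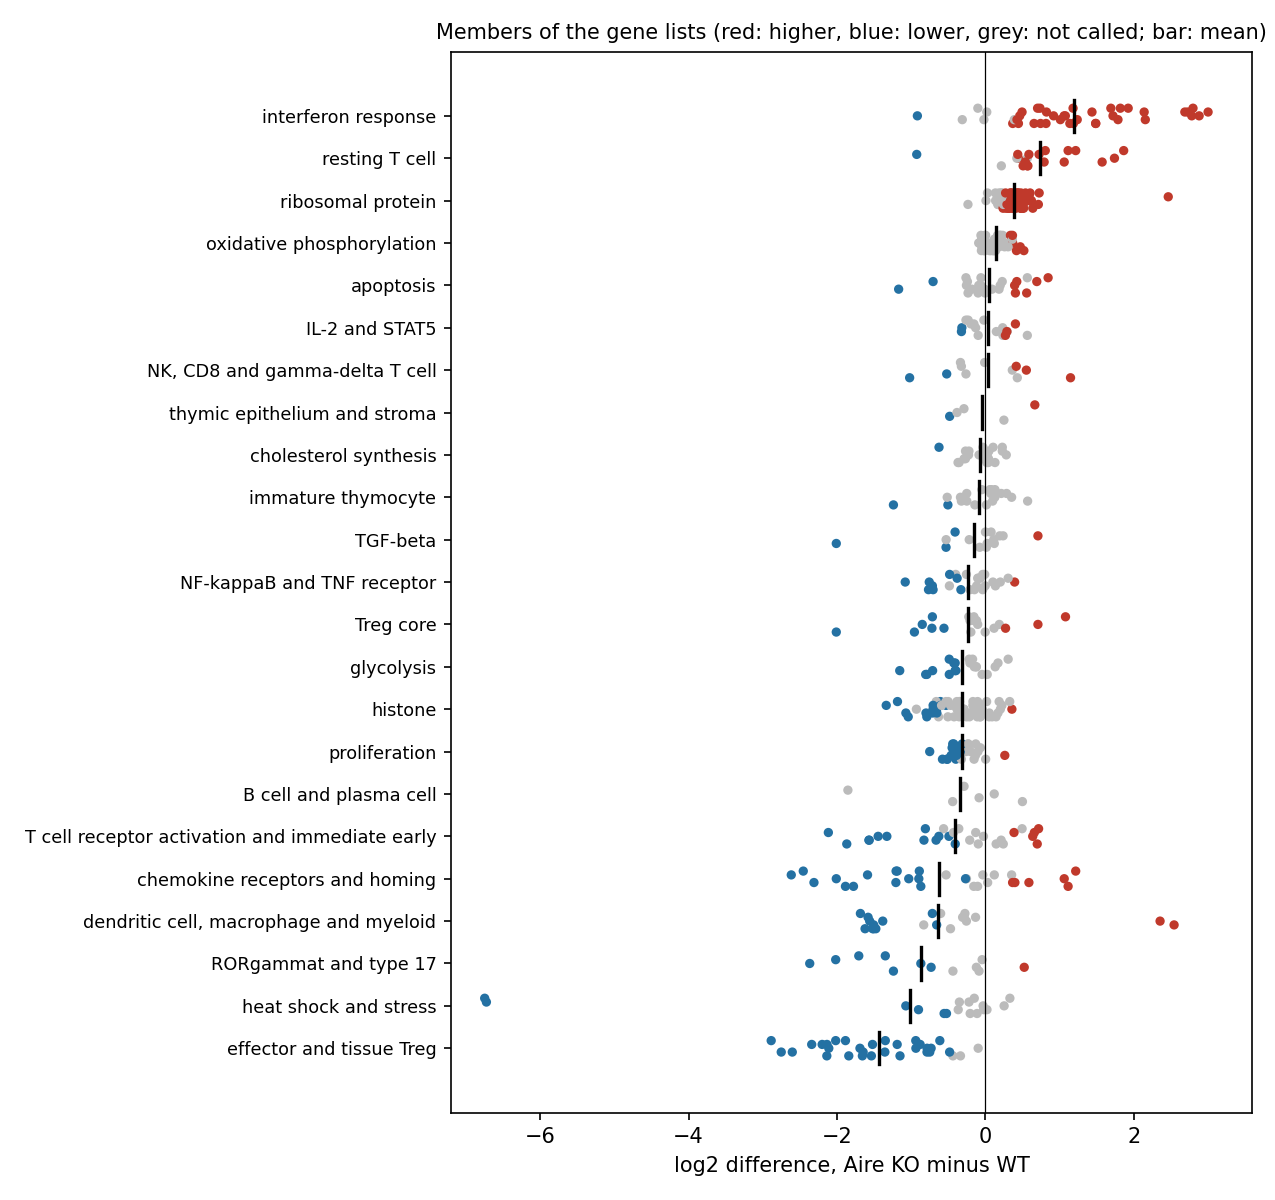
Log2 difference (Aire KO minus WT) of every measured member of the 23 tested lists, with red points higher and blue points lower at adjusted p under 0.05, grey points not passed and a bar at the list mean. Means run from 1.20 for the interferon response to -1.43 for effector and tissue Treg genes.

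A further set of lists did not pass. Of 23 cholesterol synthesis genes, 1 was lower and 0 higher over all genes, and 0 of either adjusted over the list alone (camera adjusted p = 0.585). Hmgcs1 (log2 difference 0.23) and Sqle (-0.37) did not pass, and the list passed without WT 2 (adjusted p = 0.0218; 0.0218 to 0.822 over its alternatives). Of 15 TGF-beta genes, 1 was higher and 3 lower (2 and 4 adjusted over the list alone; camera adjusted p = 0.590), with a mean of -0.15 and a median of 0.01. Lrrc32, the surface anchor of latent TGF-beta also known as GARP, rose by 0.71 on the log2 scale (167 ± 0.893 FPKM against 102 ± 1.26, SD, n = 2 each), while Itgae fell. Of 24 apoptosis genes, 6 were higher and 2 lower (8 and 4 adjusted over the list alone; camera adjusted p = 0.590, mean 0.05, median -0.01), among them the death-promoting genes Bcl2l11, which encodes BIM (log2 difference 0.85), and Pmaip1, which encodes NOXA (-1.17). Bcl2l11 did not pass without Aire KO 1 (adjusted p = 0.0533) or with no filter on low values (0.0535, the highest over its alternatives). Of 17 IL-2 and STAT5 genes, 3 were higher and 2 lower (7 and 4 adjusted over the list alone; camera adjusted p = 0.662, mean 0.04, median -0.02). Cish, a STAT5 target, had a log2 difference of -0.32 and did not pass under 4 of its 16 alternatives, without Aire KO 1 (adjusted p = 0.119), without Aire KO 2 (0.216, the highest), with no filter on low values (0.0582) and without the intensity trend (0.0686). Bcl2, at 0.57 (adjusted p = 0.0701), passed under 3 of its 16 alternatives, among them those with WT 1 left out (adjusted p = 0.00370) and with small RNA names left out (0.0103; 0.00370 to 0.299 over its alternatives).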

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

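The alternatives that left out small RNA names or crossed the replicate numbers were chosen after seeing the data. All 1751 called genes that were tested under an alternative kept their direction under each of the 16 alternatives at gene level. For many of these the direction was fixed in advance. The filters, the trend, the names kept or left out and the replicate blocks do not alter a gene's log2 difference. Only a pseudocount, a scaling or a left-out library could turn it. Leaving out 1 library gave 171 to 751 genes higher and 355 to 868 lower (lowest without Aire KO 2), where the remaining sample of a group leaves less power; 633, 493, 1281 and 1165 of the calls remained without Aire KO 1, Aire KO 2, WT 1 and WT 2. Without a filter on low values 316 genes were higher and 471 lower, with 16461 genes tested, and 662 of the calls remained. The genes past an unadjusted p of 0.05 and 1.5-fold numbered 182 higher and 351 lower with a pseudocount of 5, which shrinks the folds of low genes, and 358 lower with a mean of at least 5 FPKM, where 8273 genes were tested. With an estimated correlation, camera passed 0 lists as higher and 0 as lower (2 at an unadjusted p under 0.05). Quantile normalization gave 907 higher and 941 lower, TMM scaling 890 and 1054, and leaving out small RNA names 1156 and 1208. Same-numbered libraries did not deviate together (r = -0.108 across genes), so the numbers were not taken to pair them; the replicate block gave 554 higher and 711 lower, with 1242 calls remaining (of the named genes, Ccl5 missed at an adjusted p of 0.0501; 0.00196 to 0.188 over its alternatives) and 4 lists higher and 11 lower. Crossing the numbers (Aire KO 1 with WT 2) gave 943 and 1085. Of 94 named genes, 84 were called; none of these reversed and 61 kept the call under each alternative. Fewer libraries accounted for 34 of the 46 lost calls and the missing filter for 9. Depth, known only from interval widths, limits genes near 1 FPKM most.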

Other observations

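The tests of stress before lysis, of cells other than Tregs, of fewer myeloid cells and of male cells were chosen after the result was seen; the genes of the next paragraph and the heat shock and T lineage genes named as examples were also chosen after their values were seen.

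Several regulators outside the lists differed between the genotypes. Id2 and Id3, related inhibitors of E proteins, went opposite ways: Id2 measured 34.6 ± 3.0 FPKM in Aire KO and 192 ± 25.1 in WT, and Id3 304 ± 2.15 against 118 ± 11.3 (SD, n = 2 each; log2 differences -2.44 and 1.36, limma adjusted p = 0.000132 and 0.000389). The nucleic acid sensor Tlr7 was 3.89-fold higher, and the TRIM family gene Trim12c 2.38-fold higher. The interleukin 18 receptor subunits Il18r1 and Il18rap were 2.31-fold and 2.83-fold lower, and Il17rb, a receptor subunit for interleukin 25, was 2.60-fold lower. The transcription factors Cebpb, Runx3, Bhlhe40 and Rbpj were 5.12-fold, 2.14-fold, 2.09-fold and 1.93-fold lower.

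The fall of Hspa1a, Hspa1b and Hspa1l in Aire KO was weighed first. A difference in stress on the cells before lysis may have contributed. Without the Hspa1 genes, the 15 other heat shock and stress genes had a mean log2 difference of -0.26 (SE 0.0997 over members). Among them 4 were lower and 0 higher. Of 28 T cell receptor activation and immediate early genes 12 were lower, 5 higher (Egr1 and Ier2 included) and 11 not passed. Adjusted over these 2 lists alone, the camera p was 0.0129 and 0.00181, and 0.442 for both with an estimated correlation. Chaperone genes differed in size and sign, Hspb1 (log2 difference -1.07), Bag3 (-0.90) and Dnajb1 (-0.56) being lower and Hsp90aa1 (-0.37), Hsph1 (-0.11), Hspa8 (0.02) and Hspe1 (0.33) not past the threshold, with Hsph1 at 31.5 ± 13 and Hspa8 at 609 ± 112 FPKM in Aire KO (SD, n = 2), so whether stress would be the whole explanation stays open. A strain difference around these genes cannot be told apart from the genotype. Within 2 Mb of Hspa1a, 25 of 133 tested genes were called (18.8% against 16.3% of all tested genes, one-sided Fisher's exact p = 0.243). This neither shows nor excludes a cluster. The called genes there include H2-Ab1 and H2-Eb1 of the myeloid list and Rps18 of the ribosomal protein list. The share therefore does not measure a strain difference alone. An effect of Aire loss on the cells stays open and was not tested.

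For the rise of interferon-response genes in Aire KO, RNA from myeloid cells in the Aire KO libraries is argued against: of 9 abundant myeloid transcripts, 0 rose by as much as the 56.8 FPKM of Usp18, the largest rise being the 5.12 FPKM of S100a8, and Cst3 and Lyz2, the most abundant, differed by -29.1 and -10.1 FPKM in cells gated on CD4 and CD25. An infection or housing difference carried by 1 Aire KO library is argued against too, since the list mean rose by 1.22 in Aire KO 1 and 1.17 in Aire KO 2, a difference of 0.0422 of the mean rise. A housing, infection or litter difference shared by both Aire KO libraries is confounded with the genotype and was not tested. Interferon exposure of Tregs as a consequence of Aire loss is a biological hypothesis that stays open beside it.

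The lower Ccr6 and effector Treg genes with higher resting genes in Aire KO could come from a changed mixture of cells in the gate. However, more cells that are not Tregs would lower no gene by a larger factor than Foxp3. In log2 difference Foxp3 lay 0.72 (7.20 SE) above Ccr6 and 1.28 (8.42 SE) above the mean of the effector and tissue Treg list. The SE of a list mean, here and below, was taken over its genes, which are not independent, and not over libraries. For the resting genes, more cells that are not Tregs cannot be told apart from a change in the Tregs. Read as dilution, the Foxp3 difference allows RNA of such cells to take up to 18.9% more of the library than in WT (2 SE). This assumes the same Foxp3 level in each Treg of both genotypes, and a share of RNA is not a share of cells. Fewer myeloid cells in the Aire KO sort are argued against for the resting genes, whose mean lay 0.89 (5.78 SE) above Foxp3. Less myeloid RNA would raise the resting genes and Foxp3 alike. Of 4 effector list members of the T lineage, Icos, Tigit and Klrg1 lay below Foxp3 by at least 9.24 SE. The other, Gata3 (log2 difference -0.10), did not pass. These 4 were picked after their values were seen. They argue against fewer myeloid cells for Icos, Tigit and Klrg1 alone, not for the list. For the other 28 effector and tissue Treg genes fewer myeloid cells cannot be told apart from a change in the Tregs, as the summed FPKM of the 21 measured myeloid genes fell by 20.5% of the fall of those genes (20.0% to 21.1% over pairings of libraries), Cd74 making up 187 of 326 FPKM. More newly generated thymic cells cannot be told apart from other mixtures either: 0 of 8 markers of such cells were called higher and 0 lower by limma (1 at an unadjusted p under 0.05), 5 had a higher point value, and Sox4, at an adjusted p of 0.0502, was called higher under 6 of its 16 alternatives (0.00488 to 0.254). Of the same markers, Rag1 (log2 difference -0.51), Dntt (-0.25) and Tox (-0.05) had lower point values and were not called. A lower share of effector cells among CCR6-positive Tregs, or a lower level of Ccr6 and effector Treg genes in each cell, stays open as a biological explanation. For the lower genes, fewer cells without Foxp3 other than myeloid cells in the Aire KO sort were not tested and stay open too.

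For genes called near Aire, a strain segment carried with the Aire mutation cannot be told apart from no such segment. Within 10 Mb of Aire, 26 of 176 tested genes were called (14.8% against 16.3% of all tested genes, one-sided Fisher's exact p = 0.737 for more and 0.336 for fewer).

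Male cells in the WT libraries and not in the Aire KO libraries are a confounder of every comparison made here. As the main source of the differences they are argued against: Y-linked RNA was 9.49 to 15.1 times higher in WT 1 than in WT 2, yet WT 2 differed from Aire KO by about as much as WT 1 did. Over 444 genes at least 2-fold apart between Aire KO 1 and WT 1, which were chosen without WT 2, the FPKM difference between WT 2 and Aire KO 2 had a median of 0.957 times that between WT 1 and Aire KO 1 (quartiles 0.641 and 1.29), and over 456 genes chosen on Aire KO 2 and WT 1 the median was 1.02. An effect of sex on single genes stays open.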
